A study of Homo sapiens with 8 samples.

How the data were processed

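H3K36me3 ChIP-seq and matched input DNA were analysed from HepG2 cells carrying a control shRNA or an shRNA against SETD2, with 2 replicates in each of the 4 groups. Per the labels' protocols, shRNAs were delivered by lentivirus collected 48 and 72 h after transfection, added with 4 µg/mL polybrene, and cells were selected with 1 µg/mL puromycin. The immunoprecipitation used an Abcam antibody against H3K36me3. Whether the replicates came from separate cultures is not given in the sources used here.

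The genome build was hg19, and Bowtie 1.1.2 and FastQC 0.11.5 were used, per the submitters' processing notes. Per the file headers, peaks were called with MACS 1.4.2 from 1 merged alignment of immunoprecipitated tags against 1 merged alignment of input tags per condition. The settings were a p-value limit of 1e-05, an effective genome of 2.7 Gb, a bandwidth of 300 bp, a model fold of 10 to 30, tags of 50 bp, 1 duplicate tag per position and a fragment size of 294 bp. The larger dataset was scaled to the smaller, and the local background was taken over 1000 and 10000 bp, per the file headers. Pooling the replicates before calling left 1 list per condition, so no spread between replicates, no replicate left out in turn and no p-value between conditions could be had.

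Each condition had a table of peaks and a second, shorter list. The deposited tag counts are whole numbers of immunoprecipitated tags per peak after duplicate removal, not normalized. The deposited score of a peak is minus 10 times the log10 of its p-value against the local input background, and its lowest value was 50 in both tables. The deposited fold enrichment is the ratio of immunoprecipitated tags over that background by the authors' caller, and whether it covers the whole peak or its highest point was not checked. The deposited FDR is in percent and comes from peaks called with immunoprecipitate and input exchanged, as this caller defines it; it reached 18.8% in the control table and 92.8% in the knockdown table. The shorter lists, compared peak by peak, held exactly the 17856 control and 1244 knockdown peaks with an FDR of 5% or less. The full tables were the main lists. Header totals gave 47880817 filtered immunoprecipitated tags of 55151259 in the control and 67053273 of 76331109 in the knockdown. Filtered input tags were 67158956 of 75393078 and 69095038 of 77500412. At these depths the binomial interval of the share of tags in peaks spans under 0.05 percentage points, and intervals cover counting error only.

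From these lists, peak numbers, covered length and the share of filtered tags in peaks were computed per condition. Peaks of the lists were called shared when they overlapped by at least 1 bp. Shares carry exact Clopper-Pearson 95% intervals and were set against 100 random placements of the knockdown peaks on their own chromosomes. Control peaks with and without a knockdown peak were compared by the AUC of fold enrichment, with a 95% interval from 1000 resamplings of chromosomes. Covered length was compared on chromosomes 1 to 22 and X, which left out 41 control and 6 knockdown peaks, and in 1 Mb windows. Fold enrichment and score were used only to describe, rank or filter peaks within a list. Tag density across lists was computed as tags per kb per 1000000 filtered tags, with Poisson 95% intervals for single peaks, in pairs with a reciprocal overlap of at least 50%. Where several peaks of the other list lay over a named peak, their tags and lengths were summed.

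The comparisons, their tests and most alternatives were set before the data were examined: an FDR of 5% or less, a score of 100 or more (p of 1e-10), a fold enrichment of 5 or more, the shorter lists, 50% overlap of the peak or of both peaks, peaks merged within 3000 bp, chromosomes 1 to 22 alone, and tags per kb or width in place of fold enrichment. Chosen after the data were seen were the density of matched pairs with its alternatives, the single score limit of 227.88 in both lists, and placements within 1 Mb. For the rules that ask for 50% overlap, the placements were still scored at 1 bp, an upper bound. The rule for named peaks, set in advance, took the 5 with the highest fold enrichment in each list and the 5 highest knockdown peaks that overlap no control peak. Windows were named by an adapted form of the rule for genes: the largest covered length in each list, and the largest with 0 in the other list.

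Planned results by gene were not run: the number of marked genes, gene lists kept in the knockdown, the position of peaks along genes, and values at SETD2, MYC and the members of the fixed gene lists, markers of other lineages among them. They need gene coordinates on hg19, and the gene table used here was on GRCh38.p14, so no gene was assigned to a peak. Results therefore stay at peaks, windows and chromosomes.

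Calculations used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and plots used matplotlib 3.10.9. The steps were tested on simulated data. Of 35375 simulated peaks, part were left in place and the rest placed at random. The expected overlap was 65.3%, chance overlap from the placement step included, and 65.2% was found. With all peaks placed at random the overlap was 12.49%, against a mean of 12.53% over further random placements. These overlap figures check the counting and not the placement itself. A simulated median log2 ratio of tag counts of -0.60 over 35175 peaks came back as -0.60, and one of -2.00 over 200 changed peaks as -1.99. Simulated peaks kept their length and depth and were not called again. This checks the matching of pairs, and the division of tags by length and depth was not tested. An AUC of 0.760 was recovered as 0.756.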

Results

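Trimethylation of histone H3 at lysine 36 (H3K36me3), a mark of transcribed gene bodies, was profiled by ChIP-seq in HepG2 cells, a human hepatocellular carcinoma line. The cells stably expressed a short hairpin RNA (shRNA) against SETD2, the methyltransferase that places this mark in human cells, or a control shRNA with no specific target. The 8 libraries formed 4 groups of 2 replicates: H3K36me3 immunoprecipitate and input DNA from the control cells, and the same pair from the SETD2 knockdown cells. Both replicates of a group had been pooled before peaks were called, so there was 1 peak list per condition, no spread between replicates and no test between the conditions. The pooled immunoprecipitates held 47880817 tags in the control and 67053273 in the knockdown after removal of duplicates, and the pooled inputs held 67158956 and 69095038. The knockdown was therefore the more deeply sequenced condition. Intervals given for shares of tags or peaks are exact (Clopper-Pearson) 95% binomial intervals that cover counting error only. Positions are in hg19. No measurement of SETD2 itself was analysed here.

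The first comparison asked how many H3K36me3 peaks were called in cells with and without the SETD2 shRNA. The control list held 35375 peaks covering 229 Mb, and the knockdown list held 23488 peaks covering 111 Mb, which is 66.4% of the peaks and 48.4% of the covered length. Peaks took up 42.0% of the control immunoprecipitate (95% interval 42.02 to 42.05%) and 12.8% of the knockdown immunoprecipitate (12.76 to 12.77%), a ratio of 3.29. Each share was taken over the peaks of its own list, so the ratio also depends on how much length was called. Inside peaks the control held 1.84 tags per kb per 1000000 filtered tags, the measure of tag density used throughout, against 0.235 in the rest of the effective genome. The knockdown held 1.15 inside its peaks and 0.337 outside them.

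Wide domains made up more of the control list than of the knockdown list. Peaks of 20 kb or more numbered 2073 in the control and 326 in the knockdown, and the widest were 113 kb and 48.7 kb. The median peak was 3.66 kb wide in the control (quartiles 2.16 and 7.32 kb) and 3.27 kb in the knockdown (2.12 and 5.67 kb).

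The gap between the lists widened with the score of the peaks, which is minus 10 times the log10 of the p-value that the authors' caller gave each peak. At a score of 100 or more the knockdown held 15715 peaks and the control 26724, or 58.8%. At 500 or more the counts were 3679 and 10762 (34.2%), and at 1000 or more they were 1150 and 5683 (20.2%). Under a false discovery rate (FDR) of 5% or less the control kept 17856 peaks and the knockdown 1244, so the knockdown count fell to 6.97% of the control count. That FDR limit stood at a score of 227.88 in the control list and 939.74 in the knockdown list. With 227.88 applied to both, a limit chosen after the data were seen, the knockdown held 8570 peaks, or 48.0% of the control count. Scores did not follow fold enrichment at peaks with many tags. Of peaks with a fold enrichment of 8 or more and 2001 to 3000 tags, 19.6% in the control and 26.3% in the knockdown scored under 500. At the top, 1318 control and 96 knockdown peaks shared a score of 3100. Counts at a score limit therefore do not order the strongest peaks by strength. The same holds for the FDR limit, which acts as a score limit in each list. Knockdown peaks with 2001 to 3000 tags had a median score of 625.77, below the 939.74 of that limit, so it also leaves out strongly enriched peaks.

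**Figure D1:**
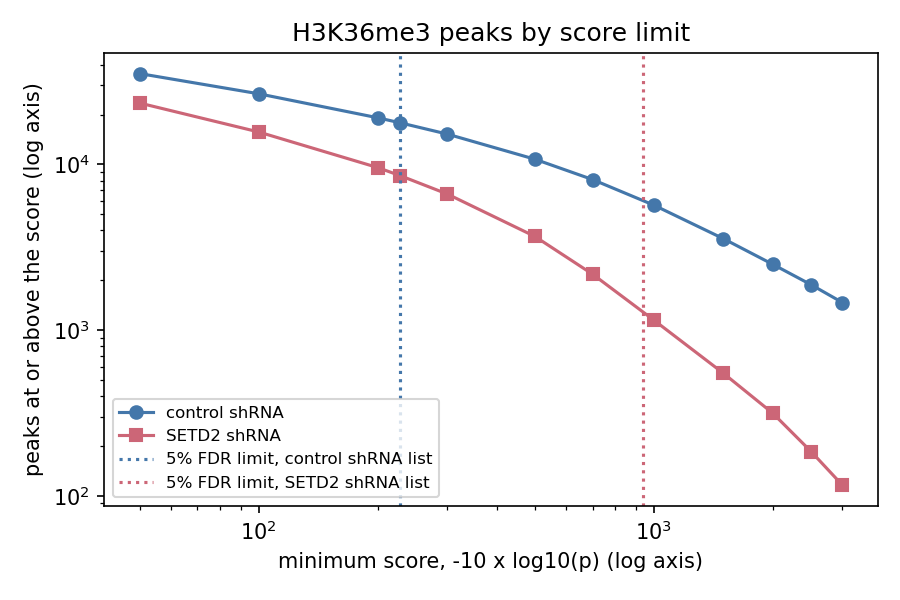
Number of H3K36me3 peaks (vertical, log axis) at or above a minimum score, minus 10 times log10(p) (horizontal, log axis), in the control shRNA list (circles) and the SETD2 shRNA list (squares). Dotted lines mark where each list reaches a 5% FDR, at scores of 227.88 and 939.74, and the lists separate from 35375 against 23488 peaks at a score of 50 to 1468 against 116 at 3000.

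The second comparison asked whether the peaks of the knockdown cells lay where the control cells had theirs. Of the 23488 knockdown peaks, 19497 overlapped a control peak by at least 1 bp, which is 83.0% (82.5 to 83.5%). The same peaks placed at random on their own chromosomes 100 times overlapped control peaks in 12.01% of cases on average and 12.54% at most (permutation of positions, one-sided p = 0.0099, the smallest that 100 placements can give). In the other direction, 13963 of the 35375 control peaks overlapped a knockdown peak, or 39.5% (39.0 to 40.0%), against 8.89% on average for the placements (the same permutation, p = 0.0099). Placements kept within 1 Mb of each peak, added after the data were seen, gave 20.7% of knockdown peaks and 14.3% of control peaks on average, also below the observed shares. The p-values describe positions within these lists and not the spread between cultures. With both lists held to an FDR of 5% or less, 93.1% of the 1244 knockdown peaks lay on a control peak and 6.35% of the 17856 control peaks were kept.

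Of the 5 control peaks with the highest fold enrichment, 4 lay on chromosome 19, and a knockdown peak overlapped each of the 5. Fold enrichments are the authors' own values per list and only rank peaks within a list. The highest was on chromosome 19 from 9635969 to 9648005, with a fold enrichment of 36.83. Its tag density was 5.20 in the control (Poisson 95% interval 5.02 to 5.39), and that of the knockdown peak over it was 1.96 (1.85 to 2.06). The next was on chromosome 19 from 52515043 to 52530004, with a tag density of 6.10 in the control (5.92 to 6.28) and 2.25 in the knockdown peak (2.15 to 2.36). The fifth, on chromosome 21 from 44833137 to 44846574, had densities of 6.33 (6.14 to 6.53) and 3.35 (3.23 to 3.47). The other two, on chromosome 19 from 797930 to 814275 and from 58695243 to 58726107, had densities of 5.74 and 4.20 in the control and 2.75 and 1.78 in the knockdown.

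The 5 knockdown peaks with the highest fold enrichment all overlapped control peaks. The first, on chromosome 9 from 33327297 to 33350293, had a tag density of 1.81 in the knockdown (1.75 to 1.88), and the control peak over it had 3.13 (3.06 to 3.19). On chromosome 12 from 53400765 to 53435420 the values were 2.71 in the knockdown (2.65 to 2.78) and 5.41 in the control (5.30 to 5.53). Of the other 3, the knockdown peak was the denser beyond counting error in 2. They were on chromosome 5 from 899705 to 929389, with 2.26 in the knockdown (2.20 to 2.33) and 1.90 in the control (1.82 to 1.99), and on chromosome 9 from 139994816 to 139999157, with 2.53 (2.36 to 2.72) and 2.21 (2.09 to 2.33). On chromosome 5 from 633704 to 650112 the densities of 1.66 (1.59 to 1.74) and 1.55 (1.47 to 1.64) had overlapping intervals. These peaks were picked for high enrichment in the knockdown, and each density was taken over the bounds of its own list's peaks.

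In the knockdown, 3991 peaks covering 17.4 Mb overlapped no control peak. Their median FDR was 76.0%, against 66.8% for the knockdown peaks on control peaks, and 72 of them had an FDR of 5% or less. The 2 highest in fold enrichment were on chromosome 10 from 5823517 to 5843460 (11.15, FDR 2.31%) and on chromosome 1 from 66820770 to 66839792 (10.27, FDR 2.44%). The next was on chromosome 11 from 3694099 to 3710050 (10.1), with the lowest FDR of these 5, at 0%. The others were on chromosome 3 from 186765560 to 186780605 (9.72, FDR 15.7%) and on chromosome 1 from 171523697 to 171551314 (9.59, FDR 73.0%).

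By their medians, control peaks that had a counterpart in the knockdown were the stronger and wider ones. Their median fold enrichment was 7.34 (quartiles 5.40 and 10.4), against 4.22 (3.62 and 5.04) for the 21412 control peaks without one. Their median width was 7.37 kb against 2.61 kb, and their median tag density in the control was 1.45 against 0.978. A kept control peak had a higher fold enrichment than a lost one with a probability of 0.848 (AUC, 95% interval 0.829 to 0.868 from 1000 resamplings of chromosomes). Across deciles of the control list by fold enrichment, the kept share rose from 8.31% (7.43 to 9.27%) in the lowest to 90.4% (89.3 to 91.3%) in the highest. Peaks are not replicates, so no p-value was computed. A weaker peak also falls below a fixed calling limit more readily, and no kept share between replicates was available as a baseline. The AUC therefore does not show that weaker sites lost more of the mark. A wide peak is more readily overlapped by 1 bp, so part of the contrast in width is built in. With at least 50% of the control peak overlapped, the AUC of fold enrichment was 0.792 (0.768 to 0.819). The kept share did not keep rising with tags: it was 91.8% at 2001 to 3000 tags and 65.4% above 5000.

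**Figure D2:**
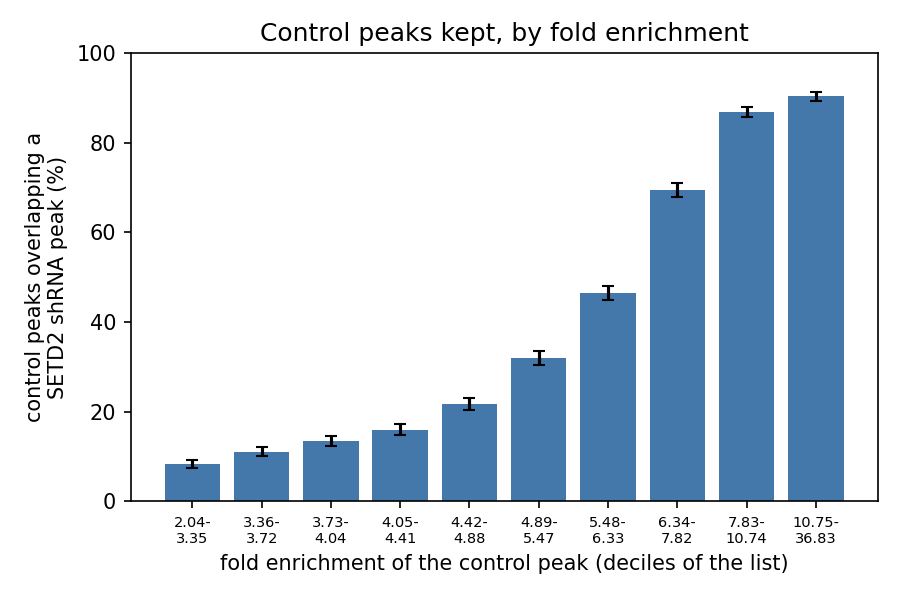
Share of control H3K36me3 peaks that overlap a SETD2 shRNA peak by at least 1 bp (vertical, percent) for each decile of the control list by fold enrichment (horizontal, range of fold enrichment). Error bars are exact 95% binomial intervals for counting error, and the share rises from 8.31% to 90.4%.

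Many control peaks that were kept were called as shorter or broken-up peaks in the knockdown. Of the kept control peaks, 10263 overlapped a single knockdown peak and 3700 (26.5%) overlapped 2 or more, with up to 11 in 1 control peak. In the other direction, 487 knockdown peaks overlapped 2 or more control peaks. Knockdown peaks covered a median of 68.5% of a kept control peak, and the lists shared 90.7 Mb, which is 39.7% of the control length and 82.0% of the knockdown length.

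Tag density was compared within peaks present in both lists, a comparison added after the data were seen. Of 7543 pairs of peaks that each overlapped the other by at least 50%, 7396 (98.1%) had a lower density in the knockdown. Each density was taken over the bounds of its own list's peak, and the knockdown peak was the narrower in 81.0% of pairs. The median log2 ratio of knockdown over control was -0.59 (95% interval -0.64 to -0.54 from resampled chromosomes), which is 1.501 times higher in the control, and the quartiles were -0.81 and -0.38. In 6070 pairs the knockdown was lower beyond counting error, and in 8 it was higher (exact conditional binomial test, two-sided, Benjamini-Hochberg adjusted p under 0.05 over all pairs). That test compares 2 pooled libraries and not the conditions. The median ratio went from -0.31 (-0.34 to -0.28) in the quartile of pairs with the lowest control fold enrichment to -0.88 (-0.92 to -0.84) in the quartile with the highest. Control fold enrichment and the control density in the ratio rest on the same tags, so part of this trend is built in. No background was taken off, and the density outside peaks was 0.235 in the control and 0.337 in the knockdown. The ratios therefore compare raw densities and not the signal above background. Control peaks that have no knockdown peak do not enter these ratios, and a scale set by an added reference chromatin was not used here.

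**Figure D3:**
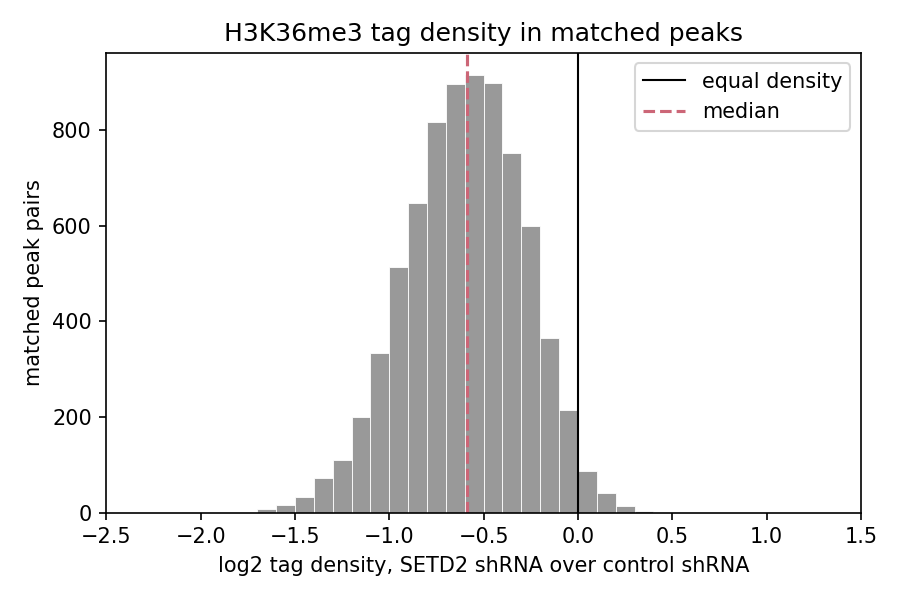
Number of matched peak pairs (vertical) by log2 ratio of tag density, tags per kb per 1000000 filtered tags in the SETD2 shRNA peak over the control shRNA peak (horizontal, bins of 0.1). The dashed line is the median at -0.59 and the solid line is equal density; 7396 of 7543 pairs lie below 0.

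The covered length was lower in the knockdown on each of chromosomes 1 to 22 and X, by amounts that differed between them. As a share of the control length, chromosome 20 fell the furthest, from 5.55 Mb in the control to 1.63 Mb (29.4%), and chromosome 1 the least, from 21.8 to 15.0 Mb (68.7%). The median over the 23 chromosomes was 47.1% (SD 9.70 between chromosomes). Low values were also found on chromosomes 4 (34.8%), 14 (35.4%), 2 (38.5%) and 6 (38.8%), and high ones on chromosomes 5 (62.5%), 12 (58.3%) and 21 (57.7%). The share of control peaks kept ran from 24.4% (20.6 to 28.5%) on chromosome 20 to 53.1% (51.4 to 54.7%) on chromosome 1. The median log2 density ratio of matched pairs was below 0 on all 23, from -0.95 on chromosome 20 to -0.46 on chromosome 1. With an FDR of 5% or less the covered length ran from 2.33% on chromosome 14 to 15.4% on chromosome 19, so the order of chromosomes changed with the limit.

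**Figure D4:**
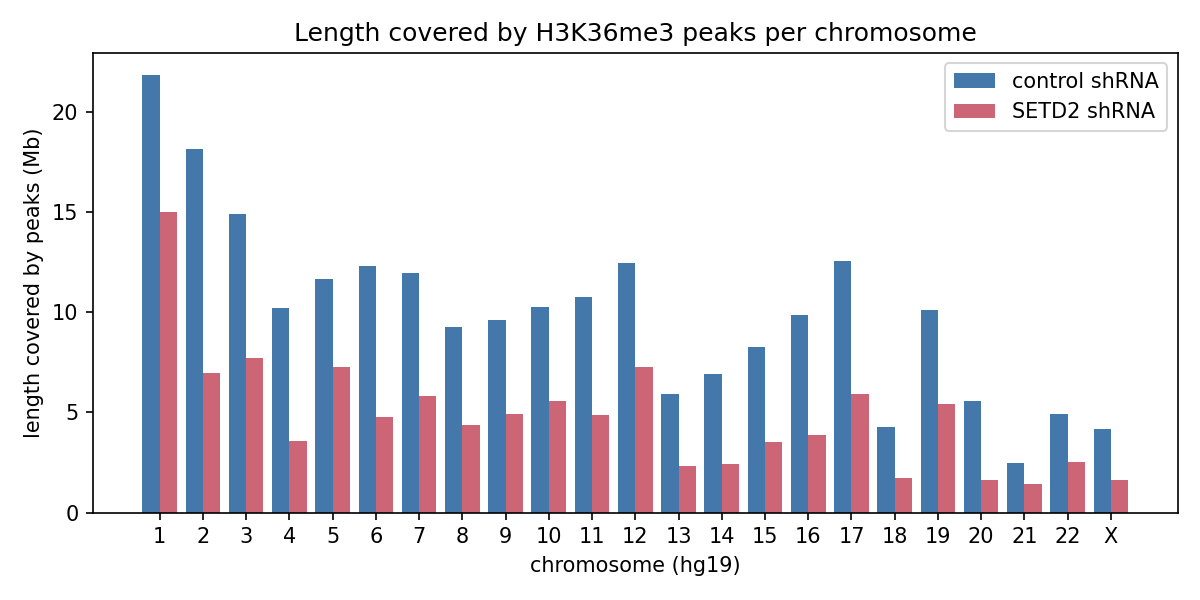
Length covered by H3K36me3 peaks (vertical, Mb) on chromosomes 1 to 22 and X (horizontal) in the control shRNA list (left bar of each pair) and the SETD2 shRNA list (right bar). There is 1 pooled list per condition and no error bar; the knockdown bar is the lower on all 23 chromosomes, from 29.4% of the control on chromosome 20 to 68.7% on chromosome 1.

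In windows of 1 Mb, 1969 of the 2171 windows with a peak in either list had less covered length in the knockdown and 202 had more. Among the 1486 windows with at least 50 kb covered in the control, the knockdown covered a median of 44.4% of the control length (quartiles 30.6 and 61.2%). The window with the most control coverage was on chromosome 16 from 89000001 to 90000000, where 438 kb in the control stood against 115 kb in the knockdown. The next was on chromosome 19 from 37000001 to 38000000, with 434 and 118 kb. The window with the most knockdown coverage was on chromosome 1 from 155000001 to 156000000, with 302 kb against 363 kb in the control, followed by chromosome 3 from 47000001 to 48000000, with 299 and 350 kb.

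Of the windows with a peak in either list, 152 had one in the control list alone and 47 in the knockdown list alone. Of the windows with at least 50 kb in the control, 11 had no knockdown peak. The 3 with the most control coverage were on chromosome 2 from 165000001 to 166000000 (98.0 kb) and on chromosome 20 from 10000001 to 11000000 (80.7 kb) and from 16000001 to 17000000 (67.0 kb). Among the 47 windows with a peak in the knockdown list alone, the largest covered length was on chromosome 1 from 66000001 to 67000000, with 187 kb in the knockdown, and the next, on chromosome 5 from 17000001 to 18000000, had 42.8 kb. Knockdown peaks with an FDR of 5% or less covered 19.0 kb of the former and 0 kb of the latter.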

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

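The single score limit in both lists, placements within 1 Mb and all settings for matched pairs were chosen after the data were seen. The knockdown list was the smaller in peaks and in covered length under all settings tried, but by how much depended on the limit. With an FDR of 5% or less, which is also what the shorter lists hold, the knockdown had 6.97% of the control peaks and 7.65% of the covered length, and chromosomes ran from 2.33% to 15.4%. The 5% FDR stood at a score of 939.74 in the knockdown against 227.88 in the control, and 227.88 in both lists gave 48.0% of the peaks and 36.4% of the length. Knockdown peaks above 5000 tags had a median score of 596.41 at a median fold enrichment of 9.54. Shares under the FDR limit therefore leave out some strongly enriched knockdown peaks. With a fold enrichment of 5 or more the shares were 24.8% of the peaks and 22.99% of the length, and chromosomes ran from 10.97% to 36.4%; the cause was not tested. Overlap stayed above all 100 placements under each setting, with 80.3 to 93.1% of knockdown peaks on control peaks except under reciprocal overlap of 50% (32.1%). The share of control peaks kept ran from 6.35% (FDR of 5% or less) to 48.6% (peaks merged within 3000 bp). The AUC of kept against lost control peaks ran from 0.792 to 0.929. The median log2 density ratio of matched pairs ran from -0.79 (FDR of 5% or less in both, 850 pairs) to -0.57 (all tags as depth). No paired analysis was possible because both replicates of each group were pooled before peak calling, which also rules out leaving out a replicate. Alternatives for results by gene were not run, since gene coordinates on hg19 were not used here.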

Other observations

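The p-value test at peaks with many tags and the relation of a stand-in for background to the kept share over its expected value were chosen only after the results were seen, as were the peaks and windows named in the next paragraph. The other tests of explanations were set before their results were computed.

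Some of the most strongly marked domains of the control had no knockdown peak over them. The 3 with the highest fold enrichment were on chromosome 19 from 6673652 to 6700359 (fold enrichment 32.22, tag density 5.96), on chromosome 8 from 8174211 to 8243926 (28.42, 4.33) and on chromosome 1 from 43390718 to 43424984 (26.94, 5.39). They held 7617, 14458 and 8848 tags. Control peaks above 5000 tags with a fold enrichment of 8 or more had scores down to 50.89, near the lowest score of 50. A missing call at such domains therefore does not show that the mark was lost. The window with the largest excess of knockdown over control length was on chromosome 1 from 66000001 to 67000000 (187 against 0 kb). It was followed by chromosome 5 from 58000001 to 59000000 (148 against 3.30 kb) and by chromosome 1 from 65000001 to 66000000 (224 against 88.7 kb). With peaks at an FDR of 5% or less, the knockdown and control lengths in these windows were 19.0 against 0 kb, 12.2 against 3.30 kb and 9.33 against 59.7 kb. Of the 10 windows with the largest excess, 5 were on chromosome 1. Apart from the first and the window on chromosome 5 from 58000001 to 59000000, all of them had more control than knockdown length at that FDR limit. Most of the excess thus rested on knockdown peaks with a higher FDR. A higher FDR goes with a lower score, and scores did not follow fold enrichment at peaks with many tags.

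Most knockdown peaks lay on control peaks in each class of FDR, but the share fell as the FDR rose. Of the 1244 with an FDR of 5% or less, 94.2% (92.8 to 95.4%) overlapped a control peak of the full list, and of the 9708 with an FDR above 75%, 78.9% (78.0 to 79.7%) did. Placements within 1 Mb gave 28.7% and 18.1% on average for these sets. Against control peaks with an FDR of 5% or less, the overlap fell further, from 93.1% to 60.7%. Placements gave 22.5% and 13.2% on average there.

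The share of control peaks kept in the knockdown differed between chromosomes, from 24.4% on chromosome 20 to 53.1% on chromosome 1. A different mix of peak strengths and widths does not account for it: after division by the share expected from fold enrichment and width, 93.8% of the relative SD between chromosomes remained (18.6% after and 19.8% before). A higher local background, as extra copies of a chromosome would give, may contribute, since the kept share was lower where control tags per kb divided by fold enrichment were higher (Spearman rho -0.62, permutation p = 0.0023, adjusted 0.0069 over 3 relations; Pearson r -0.64, p = 0.0004; 23 chromosomes; without chromosomes 2 and 20, farthest from the median, rho -0.51, p = 0.023, and r -0.46, p = 0.028). Fold enrichment enters that background and also goes with the kept share, and for the kept share over its expected value rho was -0.57 (permutation p = 0.0057, adjusted 0.0085; r -0.67, p = 0.0002) but -0.44 without chromosomes 2 and 20 (p = 0.051; r -0.37, p = 0.10): the direction held over the other 21, and the call at 0.05 rests on those 2. Copy number was not measured here, the third relation, with the density ratio of matched pairs, shares the control density with the background and was not used, and an effect of SETD2 depletion that differs between chromosomes stays open as untested.

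The knockdown list shrank far more than the control list under a 5% FDR limit, to 1244 of 23488 peaks. If the knockdown peaks with an FDR above 50% lay at random positions, they would overlap control peaks as often as placements within 1 Mb do. Of these 15444 peaks 80.8% overlapped a control peak, against 18.2 to 19.4% in 100 placements, which argues against random positions for most of them. A weaker mark left at the control positions by SETD2 depletion, and a background shaped alike in both immunoprecipitates, both stay open as untested.

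Control peaks with the most tags were kept less often than those with fewer: 91.8% (89.9 to 93.5%) at 2001 to 3000 tags, 84.9% at 3001 to 5000 and 65.4% (61.0 to 69.7%) above 5000. A candidate explanation is that p-values of the caller lose their order at such peaks: of control peaks with a fold enrichment of 8 or more, 0.281% had a score under 500 at 401 to 600 tags, 19.6% at 2001 to 3000, 20.7% at 3001 to 5000 and 27.3% (23.4 to 31.6%, 476 peaks) above 5000. The rise from 2001 to 3000 tags to above 5000 was 7.67 percentage points (2.62 to 13.2), against a fall in the kept share of 26.4 points, and in the knockdown list, where the peaks went missing, the low-score share was 11.1% of 9 peaks at 201 to 400 tags, 6.67% of 15 at 401 to 600, 0% at 601 to 1000, 3% of 100 at 1001 to 1500, 6.58% of 76 at 1501 to 2000, 26.3% of 99 at 2001 to 3000, 31.9% of 69 at 3001 to 5000 and 40.0% of 15 above 5000. Among kept peaks the median log2 density ratio was -1.17 above 5000 tags and -0.95 at 2001 to 3000, a difference of -0.22 (-0.25 to -0.19) that is smaller than the 0.5 set in advance for a selective loss of the mark. Low scores at a high fold enrichment were thus present at many tags in both lists. The 165 lost peaks have no score or tag count in the knockdown, so disordered p-values and a selective loss at these peaks cannot be told apart.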
